A study of Danio rerio with 8 samples.

How the data were processed

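RNA from the distal trunk of zebrafish larvae was sequenced at 48, 60, 72 and 96 hpf after exposure to BkF or DMSO. Per the labels' protocols, embryos had their chorions removed at 4 hpf and were exposed in 100 µL per well of 96-well plates, in the dark at 28.5 °C. Stranded libraries were read on a HiSeq 2500 as single-end reads of 100 bp. The 32 libraries form 8 conditions of 4 biological replicates. FastQC, Trimmomatic, Salmon, DESeq2 and the genome build Zv9 are named, per the submitters' processing notes, with tool versions not given in the sources used here.

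The deposited signal values are, per the labels, the authors' mean normalized counts over the 4 replicates of a condition, so each condition has 1 value per gene. They are neither whole reads nor scaled to a common total. The read depth of a sample is therefore unknown, and no counting interval is given. Salmon shares reads between near-identical copies, so values of globin, keratin and other multigene families are uncertain at the level of single genes. Some genes were listed at 0 in 1 sample and at high values in others, and 41 genes had both a 0 and a value of 100 or more.

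The comparisons, their tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The effect of BkF was tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with time point as a block, an intensity trend in the prior variance and two-sided Benjamini-Hochberg adjusted p under 0.05. Genes with a mean of 10 or more over the 8 samples entered. On this scale changes of low genes are understated. With 1 value per condition the residual is the difference of the ratio between time points. The p-values thus measure that spread, not the spread between animals or replicate pools, and they favour genes with a like ratio at all 4 times. A linear trend with hpf was fitted with treatment as a factor, and the interaction of BkF with centred hpf with time point as a factor. At single time points log2 ratios are described by size alone, a gene counting at a ratio at or beyond 1.

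38 gene lists of pathways, tissues and cell types, including tissues that the dissection should leave out, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. At single time points a list's median was set against 10000 random lists of the same size drawn from 20 bins of mean expression. Gene names came from a table of identifiers and symbols, in which 18028 of 24345 identifiers had one. Many zebrafish genes carry a capitals symbol without the paralog letter there, and 2513 identifiers share a symbol with another. The identifier is printed beside such a shared symbol. List members were matched by their own symbol (894) or else by the capitals symbol without the paralog letter (385), and 303 were not matched. This matching rule was chosen after the name table was seen and before any list result.

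The genes named were the measured AHR battery members, the 10 highest and 10 lowest BkF effects past the threshold with a mean of 50 or more, the 3 highest and 3 lowest ratios at each time point, the 2 largest changes of each list and up to 5 highest and 5 lowest slopes past the threshold. Genes without a symbol or with a clone name were passed over. Some list members were left out for length, in order, and some genes that the rule names are not reported here. Coordinates were not used here.

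Each test was first tested on simulated data built on the 21950 tested genes, with 200 of them changed. For the BkF effect 16, 62, 80 and 100% of genes changed by 0.5, 1, 2 and 4 log2 were recovered, with 7 false calls. In the data 7434 genes passed, far more than the 200 changed in the simulation, which makes the adjusted cutoff looser there. The shares for the BkF effect thus do not tell what that test recovers in the data. For the trend the shares were 60, 80, 86 and 98% with 8 false calls, and for the interaction 0, 48, 62 and 90% with 0. The simulated noise came from a fit with time point as a factor, so it held no change with time off a straight line. In the data such change enters the residual of the trend, so its shares do not tell what the trend test recovers here. Of 6 lists moved in the simulation camera recovered 6, with 0 false calls. The simulated genes varied independently of each other, whereas in the data the estimated correlation within a list reached 0.72 (skeletal muscle). The simulation therefore does not tell how many false list calls to expect here.

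Alternatives were a pseudocount of 10, no filter on low values or a mean of 50 or more, quantile normalization, the same total in every sample, no intensity trend, a robust prior, no time block, at least 2-fold change, control samples alone for the trend, and leaving out each time point. Alternatives added after the data were seen are named in the closing section. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.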

Results

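Gene expression was measured by RNA sequencing in distal trunk tissue of larval zebrafish of the Tropical 5D line. The tissue was resected at a gap in the pigment near the base of the tail and, per the labels, held the region in which an extra fin forms. Animals had been kept in 12 µM benzo[k]fluoranthene (BkF), a polycyclic aromatic hydrocarbon, or in 1% DMSO, the solvent, from 6 to 8 hours post fertilization (hpf) on. Tissue was taken at 48, 60, 72 and 96 hpf. The title of the series names the aryl hydrocarbon receptor (AHR), the ligand-activated transcription factor that senses such hydrocarbons, as the mediator of a fin duplication. The comparison of BkF with control tissue asks which transcripts differ while the extra fin forms.

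The data hold 8 samples, 1 per treatment and time point, and each is the authors' mean over 4 biological replicates of 50 animals. Replicate values were not analysed here, so no value below carries a replicate error. The spread given is the SD of the log2 ratio of BkF to control over the 4 time points. Normalized counts summed to 87750209 to 89533865 in the control samples and to 76456319 to 78634021 in the BkF samples. The read depth behind them is unknown. Of 24345 gene identifiers, 18028 had a symbol in the name table, and 21950 with a mean of 10 or more over the 8 samples were tested.

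BkF tissue differed from control tissue in 7434 genes over the 4 time points, 3624 higher and 3810 lower (limma with time point as a block, Benjamini-Hochberg adjusted). Of these, 654 were at least 2-fold higher and 842 at least 2-fold lower. Among genes named by the fixed rule, the strongest increase was that of CYP1B1, which encodes an AHR-induced cytochrome P450 enzyme, and the strongest decrease that of NOS1, the neuronal nitric oxide synthase gene. Most epidermal and periderm genes and many cartilage, matrix and hair cell genes fell. Many genes of the antioxidant response, of protein folding in the endoplasmic reticulum and of leukocytes rose. The ratio had the same sign at all 4 time points in 53% of the tested genes, where independent signs would give 12.5%. Across genes, which are not independent replicates, the ratios at 48 and 96 hpf correlated with Pearson r = 0.507 and those at 60 and 72 hpf with 0.753, the lowest and highest of the 6 pairs of time points.

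The summed normalized counts were 12.1% lower in BkF on average, and the 10 most abundant genes of the controls made up 77.8% of that difference. Among them were col1a1a (3827810.1 in controls and 2753469 in BkF, means over the 4 time points), the keratin gene krt4 (3175838 and 828215) and the fin fibre gene and2 (2070603 and 668991). With every sample rescaled to the same total, the median gene moved by 0.18 (log2) toward BkF. The count then was 10097 genes, 7946 higher and 2151 lower. Log2 changes below are on the deposited scale, relative to which the other scale lies higher by that shift. Without the 60 hpf samples 3494 genes passed, and without the 72 hpf samples 3810.

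Of the AHR battery, genes that the activated receptor is known to induce, 7 of 8 measured members rose (7 higher and 0 lower adjusted over the list alone). CYP1B1 stood at 55.0 to 102 normalized counts in the controls and 48368 to 55154 in BkF, a log2 change of 9.36 ± 0.41 (limma adjusted p = 6.91e-06). The AHR repressor gene ahrrb rose by 5.52 ± 0.74, from 5.75 to 13.4 in controls to 314 to 637 in BkF. FOXQ1, a forkhead factor gene, rose by 3.13 ± 0.37, and tiparp, which encodes an AHR-induced member of the poly-ADP-ribose polymerase family, by 2.59 ± 0.05. The forkhead genes foxf2a and foxq1b rose by 1.48 ± 0.18 and 0.95 ± 0.29. NQO1, a quinone reductase gene, rose by 0.24 ± 0.12, a call that was lost without the 48 hpf (0.22), the 60 hpf (0.23) or the 72 hpf samples (0.20). The remaining member, cyp1d1, had a log2 change of -0.16 ± 0.15 and did not pass. The list passed with camera, limma's test of a list against all other genes at a preset correlation of 0.01 (camera adjusted p = 8.15e-06; adjusted p = 0.285 with an estimated correlation). The list members cyp1a, cyp1c1, cyp1c2 and ahrra were not matched to an identifier and are not described. Among increases with no symbol in the name table, ENSDARG00000026039 stood at 342 to 625 in controls and 700404 to 758968 in BkF, and ENSDARG00000018298 at 36.7 to 84.8 and 35887 to 47767. Of the 20 largest increases, 8 had no symbol.

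**Figure D1:**
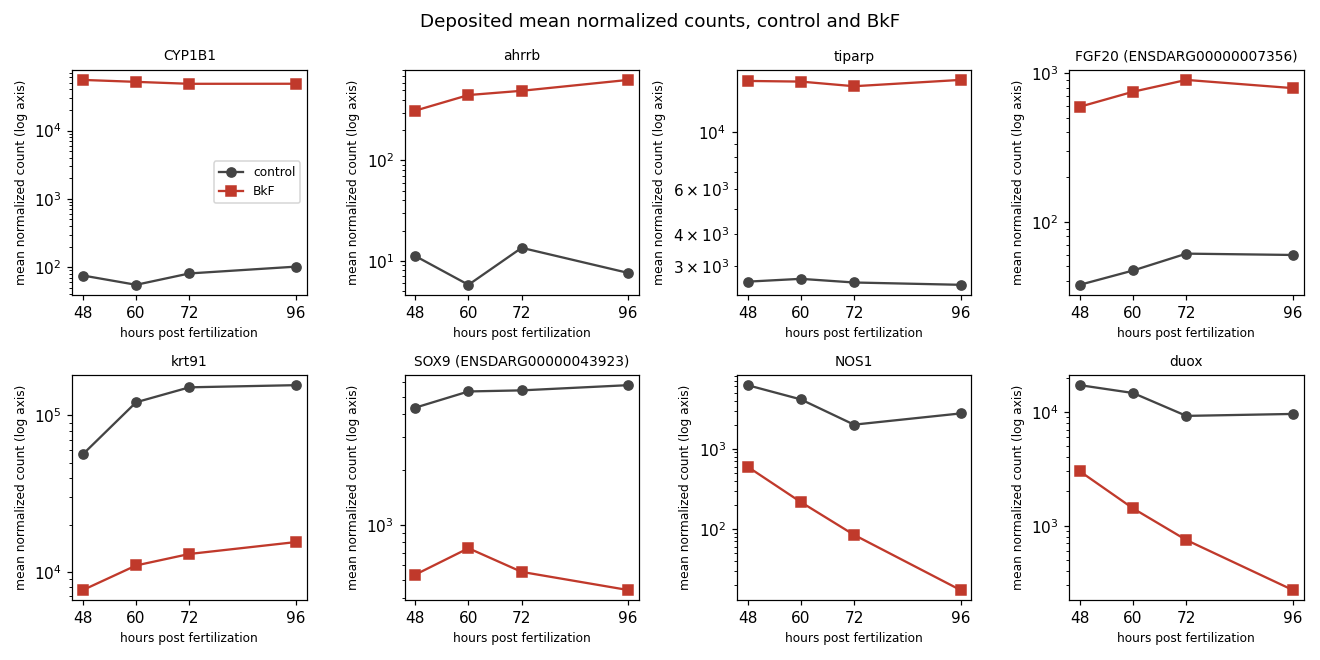
Deposited mean normalized counts (log axis) against hours post fertilization for 8 genes in control (grey circles) and BkF (red squares) tissue; each point is 1 deposited mean of 4 biological replicates and no error can be drawn. CYP1B1, ahrrb, tiparp and FGF20 were higher in BkF at all 4 time points, and krt91, SOX9, NOS1 and duox were lower, with NOS1 at 598 at 48 hpf and 17.2 at 96 hpf in BkF.

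Genes of the receptor and of detoxification also moved. Of 7 AHR receptor and partner genes 4 rose and 0 fell (4 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.132), with ahr2, which encodes a zebrafish AHR, at 0.86 ± 0.08. Among 24 other genes of xenobiotic metabolism 9 rose and 5 fell (9 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.338). The sulfotransferase gene sult6b1 rose by 2.51 ± 0.09 and the glucuronosyltransferase gene UGT1A1 by 2.44 ± 0.47. Of 23 genes of the NRF2 and antioxidant list 15 rose and 1 fell (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.80e-06; adjusted p = 0.378 with an estimated correlation). The glutathione peroxidase gene gpx1b rose by 2.02 ± 0.52 and nfe2l2b, an NRF2 paralog gene, by 1.91 ± 0.46.

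Outside the AHR battery, the growth factor gene fgf7 rose by 6.11 ± 0.22, from 49.3 to 61.0 in controls to 3633 to 4921 in BkF. The leptin gene lepb rose to 39.8, 115, 248 and 627 in BkF at the successive time points, with controls at 0, 4.82, 0 and 8.74. BMP8A, a bone morphogenetic protein gene, rose by 5.68 ± 0.46. Next came slc5a3a, a solute carrier gene (5.30 ± 0.32), lamb3, a laminin gene (4.99 ± 1.75), and PKHD1L1 (ENSDARG00000091116) at 4.87 ± 0.27. The glucagon gene gcga rose by 4.59 ± 0.66 and ugt1b1, a glucuronosyltransferase gene, by 4.44 ± 0.16. Adjusted p ran from 6.91e-06 to 0.00291 for these 8 genes (limma).

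The largest named decreases included enzymes that make reactive oxygen or nitric oxide. NOS1 had a log2 change of -4.86 ± 1.67, the dual oxidase gene duox -3.66 ± 1.09 and its maturation factor gene DUOXA1 -4.71 ± 0.97. In BkF, NOS1 stood at 598, 216, 84.2 and 17.2 at the successive time points, against 6227, 4138, 2000.2 and 2762 in controls. The others were fasn2 (-3.83 ± 0.36), the complement factor gene cfd (-3.83 ± 1.70), CPNE5 (ENSDARG00000070919) at -3.72 ± 0.30 and cspg4bb (-3.63 ± 0.76). The gap junction gene gjc4a.2 had -3.37 ± 0.82, the mitochondrial uncoupling gene UCP1 -3.36 ± 1.19 and krt91, a keratin gene, -3.31 ± 0.29. Adjusted p ran from 7.84e-05 to 0.00589 for these 10 genes (limma). Among genes with no symbol, ENSDARG00000077216 had -2.73 ± 0.82 and ENSDARG00000035791 -2.73 ± 1.15.

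Epidermal and periderm genes, which mark the outer skin layers, fell in 38 of 53 measured members and rose in 0 (1 higher and 39 lower adjusted over the list alone; camera adjusted p = 3.48e-12; adjusted p = 0.285 with an estimated correlation). The keratin genes krt91 and cyt1l led, the latter with a log2 change of -2.61 ± 0.91, from 1084680 to 1384730 in controls to 76672 to 421589 in BkF. The median change of the list was -0.60, and it was -0.56, -0.55, -0.54 and -0.68 at the successive time points. Of 31 lateral line and hair cell genes, which mark the mechanosensory organs of the skin, 20 fell and 2 rose (2 higher and 23 lower adjusted over the list alone; camera adjusted p = 7.39e-06; adjusted p = 0.549 with an estimated correlation). LOXHD1 (ENSDARG00000094738), a hair cell gene, had -1.63 ± 0.30 and the chemokine receptor gene CXCR4 (ENSDARG00000057633) -1.50 ± 0.13. Other entries of these symbols in the list did not pass, LOXHD1 (ENSDARG00000074638) at -0.22 ± 0.17 and CXCR4 (ENSDARG00000041959) at 0.19 ± 0.65. Among 31 ionocyte genes 11 fell and 6 rose (7 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.266). The ionocyte factor genes foxi3a and foxi3b had -2.79 ± 0.99 and -2.34 ± 1.16.

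Skeletal and matrix genes fell more often than they rose. Of 57 collagen and matrix genes 28 fell and 8 rose (9 higher and 30 lower adjusted over the list alone; camera adjusted p = 0.00441; adjusted p = 0.398 with an estimated correlation). The members with the largest changes went the other way, FN1 (ENSDARG00000006526), a fibronectin gene, at 2.13 ± 0.70 and CRISPLD2, which encodes a secreted protein, at 2.04 ± 0.52. Of 34 cartilage and bone genes 14 fell and 5 rose (5 higher and 15 lower adjusted over the list alone; camera adjusted p = 0.0426; adjusted p = 0.796 with an estimated correlation). SOX9 (ENSDARG00000043923), a gene of a chondrogenic transcription factor, had -3.22 ± 0.38 and the aggrecan gene acana -1.72 ± 0.64. The call of this list ended after quantile normalization (median -0.39) and with members matched by their own symbols alone (-0.29). Of 24 notochord genes 8 fell and 0 rose (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.00907; adjusted p = 0.796 with an estimated correlation), with medians of -0.27, -0.17, -0.38 and -0.96 at the successive time points. That call was lost with own symbols alone (12 genes, median -0.67). MATN3 (ENSDARG00000069245), a matrilin gene, had -1.1 ± 0.48, and noto, a notochord factor gene, had 1.3 ± 1.04 and passed only without the 96 hpf samples (1.82) or with the same total in every sample (1.47). Matrix proteases and their inhibitors rose in 12 of 32 and fell in 8 (12 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.456), with the collagenase gene mmp13a at 3.53 ± 1.26 and ADAMTS8 (ENSDARG00000058252) at -2.03 ± 0.33.

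**Figure D2:**
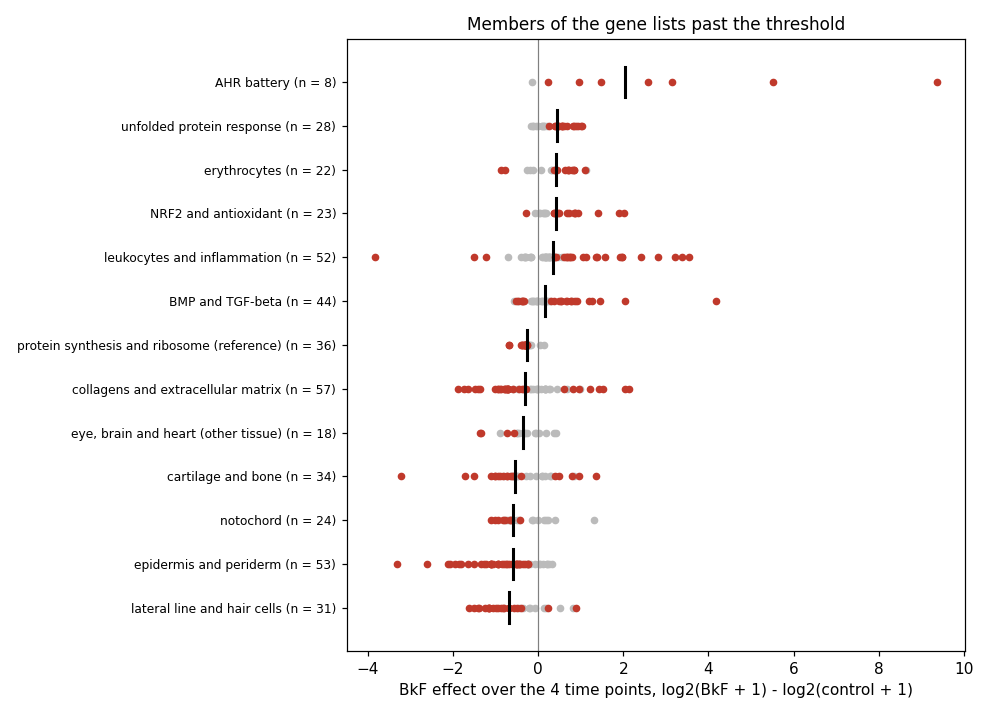
Members of the 13 gene lists past the camera threshold, each point the log2 change of 1 gene between BkF and control over the 4 time points; red points passed the limma threshold, grey points did not, and the black bar is the list's median. The AHR battery has a median of 2.03, and the epidermis and periderm list has a median of -0.60 with 38 of 53 members lower and 0 higher.

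Signals that pattern fins moved in both directions. Of 44 BMP and TGF-beta genes 16 rose and 6 fell (17 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0126; adjusted p = 0.796 with an estimated correlation). The call of the list ended without the 96 hpf samples (median 0.10) and with own symbols alone (0.17). Of 23 FGF genes 9 rose and 5 fell (10 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.224). FGF20 (ENSDARG00000007356), whose family includes a signal of fin regeneration, rose by 3.88 ± 0.12, from 37.6 to 60.9 in controls to 596 to 904 in BkF, and FGF16 by 1.58 ± 0.53. In the retinoic acid list 6 of 26 rose and 3 fell (6 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.645). The retinoic acid synthesis genes ALDH1A3 and ALDH1A2 rose by 3.87 ± 0.54 and 2.91 ± 0.59. Of 51 Wnt genes 15 rose and 21 fell (18 higher and 22 lower adjusted over the list alone; camera adjusted p = 0.456), with the transcription factor gene LEF1 at 2.01 ± 0.11 and WNT7A (ENSDARG00000044827) at -1.90 ± 0.21.

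Of 48 fin fold and fin mesenchyme genes 13 rose and 14 fell (14 higher and 17 lower adjusted over the list alone; camera adjusted p = 0.901). JUNB, an AP-1 factor gene, rose by 2.29 ± 0.52 and the homeobox gene dlx4b by 2.08 ± 0.38. Of 24 posterior Hox and tail identity genes 2 rose and 4 fell (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.266). The members that rose were msgn1, a gene of presomitic mesoderm (2.43 ± 0.77), and hoxd13a (1.15 ± 0.24). Of 19 Hedgehog genes 4 rose and 7 fell (4 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.456), and the forkhead gene FOXF1 had 1.72 ± 0.28. Of 27 Notch genes 4 rose and 3 fell (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.401). The Notch targets her4.1 (-0.96 ± 0.87) and her4.2 (-0.79 ± 1.03) did not pass, the former except without the 48 hpf samples (-1.25).

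Immune and blood genes rose more often than they fell. Of 52 leukocyte and inflammation genes 22 rose and 3 fell (22 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.000382; adjusted p = 0.796 with an estimated correlation). The largest changes in this list were those of mmp13a, upward, and cfd, downward. Of 22 erythrocyte genes 10 rose and 2 fell (12 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.796 with an estimated correlation). The nucleotidase gene nt5c2l1 rose by 1.1 ± 0.38, and the globin gene hbae5 had 1.11 ± 1.43 and did not pass. The erythrocyte call ended with every sample rescaled to the same total (median 0.61). Of 36 vascular genes 9 rose and 4 fell (9 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.338).

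Of 28 genes of the unfolded protein response 18 rose and 0 fell (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.94e-05; adjusted p = 0.796 with an estimated correlation). The list's median was 0.09, 0.44, 0.55 and 0.62 at the successive time points. DNAJB9 (ENSDARG00000016886), a chaperone gene, rose by 1.02 ± 0.48 and MANF, which encodes a secreted factor of the endoplasmic reticulum, by 1.01 ± 0.39. Of 31 heat shock genes 8 rose and 2 fell (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.337), led by hspb6 at 1.25 ± 0.45 and HSPA4 (ENSDARG00000004754) at 1.1 ± 0.22. In the list of p53 and apoptosis 10 of 37 rose and 6 fell (14 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.335), with bcl2l10 at 1.60 ± 0.59. The hypoxia list had 8 of 32 higher and 2 lower (8 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.456). Of 31 stress hormone genes 9 rose and 4 fell (9 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.199), and the list passed as higher without the 72 hpf samples (median 0.42). Proliferation genes rose in 0 of 52 and fell in 5 (0 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.456), among them STMN1 (ENSDARG00000004169) at -0.86 ± 0.07. That list passed as lower without the 72 hpf samples (median -0.09). Sterol and lipid synthesis genes rose in 3 of 40 and fell in 14 (3 higher and 14 lower adjusted over the list alone; camera adjusted p = 0.0709), and passed as lower without the 48 hpf (median -0.43) or the 96 hpf samples (-0.25).

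Of 36 ribosomal and reference genes 17 fell and 0 rose (0 higher and 25 lower adjusted over the list alone; camera adjusted p = 4.59e-06; adjusted p = 0.796 with an estimated correlation). The actin genes actb1 and actb2 had -0.69 ± 0.16 and -0.69 ± 0.11 and lost their calls after quantile normalization (-0.08 and -0.12) and without the 60 hpf samples (-0.70 and -0.67). The call of the list also ended after quantile normalization (median -0.11). Swapping BkF and control at 2 of the 4 time points, which cancels an effect of the same size at all times but not differences between times, gave 11, 12 and 14 lists past the camera threshold against 13 with the real labels. With an estimated correlation 0 lists passed. With fry, which asks whether the genes of a list move one way on balance and does not set them against other genes, 8 of the 13 lists passed. The exceptions were the notochord (fry adjusted p = 0.0846), erythrocyte (0.0876), unfolded protein response (0.113), eye, brain and heart (0.0746) and ribosomal lists (0.0786). A further 5 passed as higher with fry alone: AHR receptors and partners (0.00118), other xenobiotic enzymes (0.0179), retinoic acid (0.00380, with a median of -0.02 and a mean of 0.29), FGF (0.00222) and heat shock (0.0456). The heat shock list had a median change of 0.004 and a mean of 0.08.

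Markers of deeper trunk tissue had a lower median ratio at 96 hpf than before. The median ratio of 59 skeletal muscle genes was 0.33, 0.24, 0.00 and -0.66 at the successive time points, and 8 rose and 7 fell over the time points together (6 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.765). Without the 96 hpf samples the muscle list passed as higher (median 0.23). CAPN3 (ENSDARG00000043035), a muscle protease gene, had 1.17 ± 0.22. For 58 neuron and glia genes the medians were 0.08, 0.13, 0.16 and -0.66, with 5 higher and 13 lower (5 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.267). The myelin gene mbpa stood at 0, 63.2, 525 and 613 in controls and 0, 0, 21.7 and 129.6 in BkF, a decrease whose call was lost without the 60 hpf (-2.26), the 72 hpf (-2.75) or the 96 hpf samples (-3.51). MAP1B, a microtubule gene, had 1.68 ± 0.91. Of 23 genes of myogenic progenitors 1 rose and 7 fell (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0687), with PRDM1 at 1.68 ± 0.36. This list passed as lower without the 48 hpf (median -0.29), the 60 hpf (-0.26) or the 72 hpf samples (-0.29). The medians at 96 hpf of the muscle, neuron, myogenic progenitor and notochord lists each stood at percentile 0 among 10000 random lists of like expression. So did those of the Wnt, posterior Hox, cartilage and bone, epidermis, ionocyte and lateral line lists, so this was not particular to deeper trunk tissue. The muscle list had stood at percentile 100 at 48 and 60 hpf. Genes of a random list need not move together as those of a tissue may.

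Other tissues were checked in the same way. Of 33 pigment cell genes 5 rose and 4 fell (2 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.772), with the iridophore genes pnp4a at -1.65 ± 0.63 and ltk at -1.1 ± 0.32. Of 18 pronephros and cloaca genes 3 rose and 3 fell (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.804), with SLC20A1 (ENSDARG00000020114) at 1.49 ± 0.71 and the water channel gene AQP3 at -1.1 ± 0.02. Of 18 eye, brain and heart genes 4 fell and 0 rose (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0476; adjusted p = 0.786 with an estimated correlation), with the forebrain factor gene DLX1 at -1.37 ± 0.43. That call ended after quantile normalization (median -0.27), without the 96 hpf samples (-0.19) and with own symbols alone (-0.46). Of 26 liver, pancreas and gut genes 3 rose and 8 fell (3 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.456). Their median was 0.87, -0.49, -0.75 and -0.59 at the successive time points. The apolipoprotein gene apoa2 stood at 1.09 to 4.88 in the controls, at 1099.5 in BkF at 48 hpf and at 16.9 to 26.3 in BkF later. Of 40 clock genes 7 rose and 9 fell (8 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.511), and their median was 0.08, -0.07, -0.35 and 0.09. NR1D1, a clock repressor gene, had log2 ratios of 2.45, 1.83, -0.80 and 1.67 and passed only without the 72 hpf samples (1.98), and dbpa, a clock output gene, had ratios of -0.25, -1.11, -2.39 and -0.32 and did not pass. The median and mean of a list differed in sign for retinoic acid (-0.02 and 0.29), fin fold (-0.02 and 0.05), skeletal muscle (-0.02 and 0.09), pigment cells (0.03 and -0.02) and liver, pancreas and gut (-0.20 and 0.20).

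**Figure D3:**
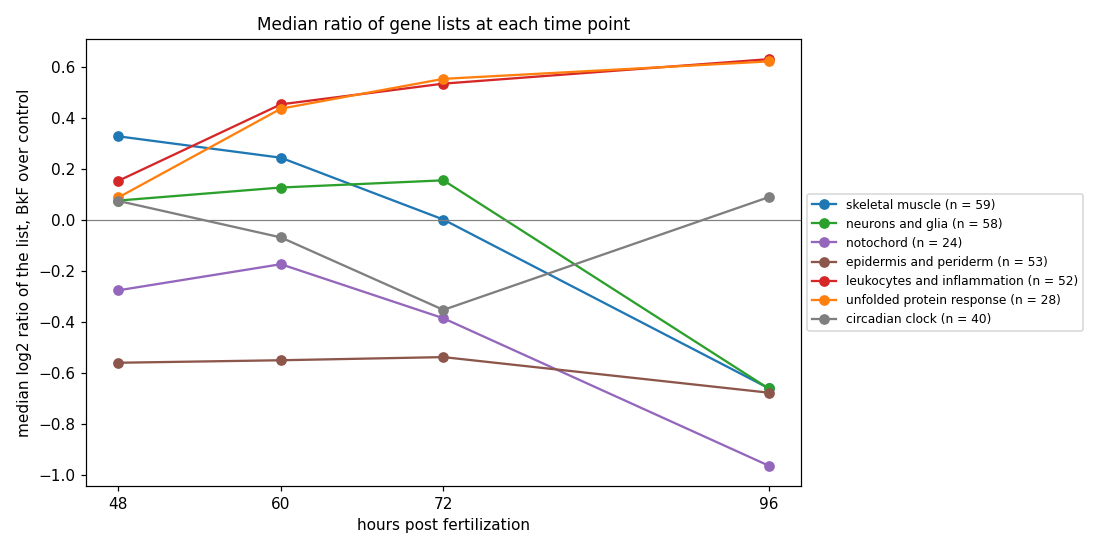
Median log2 ratio of BkF over control (vertical axis) of 7 gene lists at each time point in hours post fertilization (horizontal axis); each point is the median over the list's measured genes in 1 pair of deposited samples. Skeletal muscle went from 0.33 at 48 hpf to -0.66 at 96 hpf and neurons and glia from 0.08 to -0.66, while epidermis and periderm stayed between -0.68 and -0.54.

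At single time points, which have 1 value per treatment and so no test, the number of genes at 2-fold or more was 1702, 2019, 2448 and 3071 at 48, 60, 72 and 96 hpf. Higher genes numbered 798, 922, 1072 and 1162, and lower genes 904, 1097, 1376 and 1909. At all 4 time points 320 genes were at least 2-fold higher and 324 at least 2-fold lower. CYP1B1 was among the 3 highest ratios of named genes at every time point (9.50, 9.85, 9.21 and 8.88). At 48 hpf the other two were apoa2 (7.97) and apobb.2 (7.68), both apolipoprotein genes. At 60 hpf they were BMP8A (6.26) and OXGR1 (ENSDARG00000033684), and at 72 hpf lepb and OXGR1. OXGR1 was listed at 1.11, 0, 0 and 3.22 in the controls and 32.3, 74.0, 109.9 and 154 in BkF, and no fold is given for it or for lepb. At 96 hpf they were fgf7 (6.37) and MRPS22, which was listed at 0, 821, 908 and 0 in the controls and 114, 878, 1319.8 and 1221 in BkF. The lowest ratios included fasn2 (-4.02) and fam169aa (-3.84) at 48 hpf, NEU3 (ENSDARG00000096381) at 84.1 in the control and 0 in BkF and kcnt2a (-4.54) at 60 hpf. At 72 hpf sparcl2 (-5.04), DUOXA1 (-4.88) and cfd (-4.85) were lowest, and at 96 hpf NOS1 (-7.24) and DUOXA1 (-5.89) with ERLEC1. ERLEC1 was listed at 1023, 0, 0 and 239.9 in the controls and at 0 in every BkF sample, so no fold is given.

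A linear change with developmental time, shared by both treatments, passed in 1 gene, epdl1, an ependymin-like gene (limma, adjusted p = 0.0129). It rose by 0.81 ± 0.06 (log2 per 24 h ± SE), from 1074 at 48 hpf to 3147 at 96 hpf in controls and from 1249.6 to 4179 in BkF. At an unadjusted p under 0.05 there were 6412 genes. The call was lost without the 48 or the 60 hpf samples (0 genes each), while 25 genes passed without the 72 hpf and 3934 without the 96 hpf samples. With time as a factor, chosen after the data were seen, 845 genes passed.

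The BkF effect changed linearly with time in 3 genes, all toward lower BkF values at later times (limma, adjusted p = 0.0333 for each), and 3633 had an unadjusted p under 0.05. The slope was -1.21 ± 0.07 (log2 per 24 h ± SE) for the mucin gene muc5.2 and -0.96 ± 0.05 for the troponin gene tnnt2d. The other was si:ch211-76l23.4, a clone name outside the naming rule and named after its values were seen, at -1.53. The mucin gene had log2 ratios of 0.38, -0.03, -0.67 and -2.0 at the successive time points, and tnnt2d -0.17, -0.60, -1.16 and -2.07. With no intensity trend in the prior variance 0 genes passed.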

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

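The tests of the clock genes were chosen only after the result was seen, while those of the liver and of the deeper trunk genes were written down before their values were looked at. In the test of the BkF by time interaction (limma) the difference between time points itself passed for tnnt2d (-0.96 log2 per 24 h), muc5.2 (-1.21) and si:ch211-76l23.4 (-1.53). The ratio of kcnt2a ran from 1.14 down to -4.54 between time points. Its linear interaction with time did not pass (0.71 ± 1.26 log2 per 24 h, adjusted p = 0.827). The difference of direction between single time points was not tested, since each condition has 1 value.

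At 48 hpf, BkF tissue held apolipoprotein transcripts of yolk and liver, with apoa1a at 25.9 in the control and 3097 in BkF, apoa2 at 3.39 and 1099.5 and apobb.1 at 27.8 and 933. A second list of liver genes was not higher later, its medians at 60, 72 and 96 hpf averaging -0.26 (interval -0.93 to 0.16), where under 0.25 was written down against a lasting effect of BkF. For part of the apolipoprotein genes such an effect stays open all the same, a reading settled on after the values were seen. The median of the second list was 0.15 at 48 hpf itself, so it did not follow the apolipoproteins. Of the 7 genes with apolipoprotein symbols that were 2-fold higher at 48 hpf, apoa2 alone was 2-fold higher at each later time (log2 ratio 1.61, 2.02 and 3.71 at 60, 72 and 96 hpf). The rise did not last in apoa1a (-0.53, 0.31 and -1.41) or apobb.2 (-0.30, -0.13 and -0.23), at low values in both treatments by then. Below 2-fold at 48 hpf (0.98 and 0.75), apoc1 (2.36, 3.44 and 3.19) and apoeb (1.32, 1.49 and 1.84) were 2-fold higher at each later time, as apoa2 was. RNA from yolk or liver in that sample may be the source: the median of the second list at 48 hpf lay 0.41 above its later mean, where at least 1 was written down for this explanation and under 0.5 against it. The value is on the side against it, but its interval (0.13 to 0.97) spans 0.5, so the reading that it decides nothing was settled on after the value was seen. Of the 29 measured genes 20 stood at 10 or more in every control, a baseline that could hide a small share, and 10 were 2-fold higher at 48 hpf against 4, 5 and 4 later.

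At 96 hpf, relative to the 3 earlier times, the median ratio of skeletal muscle genes shifted by -0.94 (58 of 59 lower), that of neuron genes by -0.70 and that of notochord genes by -0.81. Pronephros and cloaca genes shifted by -0.43, and vascular (-0.04) and epidermal genes (-0.10) shifted less. Outside the deeper trunk, the ionocyte and lateral line lists also had their lowest medians at 96 hpf (-0.80 and -1.09). Scaling is argued against, since the muscle median at 96 hpf was -0.65 after quantile normalization. Severing the BkF trunks nearer to the tail tip at 96 hpf is a candidate explanation: the 4 Hox genes of group 13 shifted by -0.05 and the 29 of groups 1 to 10 by -0.83, a difference of 0.78 (interval 0.37 to 0.99) of the predicted sign. A loss of deeper trunk tissue under BkF stays open, as anterior Hox genes may be expressed in that same tissue.

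At 72 hpf, 35 of 40 clock genes had a lower ratio than their mean at the other times, a difference in medians of -0.38 (interval -0.66 to -0.15). An effect of BkF of the same size at all times would leave the departure near 0. Gene by gene its median was -0.39 (interval -0.62 to -0.26). This form of the test was settled on after the value was seen, and the interval of the difference in medians spans the bound written for it. It also restates the dip that prompted the test, over genes that may move together in 1 pair of samples. No conclusion is drawn from it. An effect at 72 hpf alone was not tested. Different hours of collection of the control and BkF animals at 72 hpf could give such a pattern: across the clock genes, which are not independent replicates, it went with the departure of the 60 hpf samples from those at 48 and 96 hpf (Pearson r = 0.732, Spearman rho = 0.514). The absolute r stood at percentile 98.1 among 10000 random lists. Hours of collection are not given in the sources used here.

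Within time points, BkF and control can be swapped in 8 ways with the real one, too few for a share under 0.05. Of the others, 4 swap 1 time point and keep part of an effect that is equal at all times, and 3 swap 2 and cancel it. The real labels gave 7434 genes, with 1 of the 8 ways giving as many, and the highest of the others gave 0. A swap puts the BkF effect into the residual, so few calls were to be expected under any of them and that count carries little information. For gene lists with camera the real labels gave 13, with 5 of the 8 ways giving as many, and the highest other gave 17. Among these 13 lists, picked for passing with the real labels, that of leukocytes had a larger absolute median under another swap (0.41 against 0.35). The other 12 did not, which says little for lists so picked. Splits of the 8 samples into 4 and 4 that ignore time number 35, of which 32 could be fitted beside the time block. Of these 1 gave as many genes (highest other 0) and 17 gave as many lists (highest other 19).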

How the results depend on the processing

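Lists matched by their own symbols alone, lists and named genes at the same total, time as a factor and leaving out genes listed at 0 were chosen only after the data were seen. Between replicates no paired analysis was possible because only their mean was used for each condition. BkF and control were paired by time point alone, through the time block of every test of the BkF effect but 1 alternative (5386 genes). The cause was not tested for any change below unless given.

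The count of genes that differ between BkF and control was within 1.5 times of 7434 under every setting except at least 2-fold change (1496, a narrower criterion) and leaving out the 60 or 72 hpf samples, with 3494 to 6895 genes over the 4 time points left out in turn. Among the 7434 genes, estimates of the opposite sign numbered 2 after quantile normalization, 77 at the same total and 0 under the other settings. The share of higher calls was 48.7% on the deposited scale and 78.7% at the same total. Each share depends on its scale, the median gene shifting by -0.005 on the deposited one and by 0.18 at the same total. Of the 7434 calls 5774 were shared at the same total. The trend gave 1 gene, 0 with no intensity trend and 0 in control samples alone (both limma; 6412 at an unadjusted p under 0.05 with all samples), 845 with time as a factor (5134 unadjusted) and 0 to 3934 with a time point left out. The interaction gave 3 genes, 7 with no filter and 0 with no intensity trend. At 48 hpf, genes at 2-fold or more numbered 2669 with no filter and 1014 at a mean of 50 or more, and at 60 hpf 1310 at a mean of 50 or more, since these filters change the genes counted.

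Of the 13 lists past the threshold 0 passed with an estimated correlation and 10 passed after quantile normalization. With own symbols alone 10 lists passed: the calls of BMP and TGF-beta, notochord, cartilage and bone, and eye, brain and heart were lost and that of ionocytes was gained. No list past the threshold changed direction under any alternative. The estimated correlation gave the highest adjusted p of each (limma). Over the other alternatives it ran from 1.55e-06 to 0.000206 for the AHR battery, 1.12e-15 to 3.50e-09 for epidermis and periderm, 6.59e-05 to 0.0273 for collagens and matrix and 1.70e-05 to 0.0270 for leukocytes. Of 103 named genes 89 passed, 74 of them under every alternative run, and 89 kept their direction. Leaving out the 48, 60, 72 or 96 hpf samples ended the calls of 5, 13, 12 and 4 named genes. The unknown read depth limits what can be said of genes with low values.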

Other observations

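The gene families by symbol were grouped and tested only after the data were seen, as were the further intervals in the test of delayed development, whose first form was written down before its result. Proteasome genes were higher in BkF: 9 of 9 psma genes (median log2 change 0.46), 8 of 11 psmb (0.58), 7 of 8 psmc (0.54) and 12 of 13 psmd genes (0.56) rose, and 0 fell. Genes of mitochondrial ribosomes rose in 24 of 43 (mrpl, 0.22) and 9 of 22 (mrps, 0.19), and genes of mitochondrial import in 10 of 13 (timm, 0.31). Cilia genes rose in 16 of 29 (cfap, 0.36) and 7 of 13 (ift, 0.26), the cfap median at 96 hpf being 0.05. Collagen genes fell in 26 of 48 (-0.67; 2 rose), keratin genes in 12 of 17 (-0.85; 2 rose) and hoxc homeobox genes in 5 of 11 (-0.48; 0 rose). The hoxc fall was not of like size at all times in each gene. HOXC8 had log2 ratios of -0.38, -0.45, -0.49 and -1.27 at the successive time points, and HOXC9 had -0.82, -1.15, -1.12 and -1.15.

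Of 290 such families 30 passed with camera at the preset correlation, 20 higher and 10 lower, and 0 with an estimated correlation (limma). Swaps of the labels at 2 of the 4 time points, which cancel an effect of the same size at all times, gave 1, 5 and 13 families, and swaps at 1 time point, which keep part of it, 9, 19, 19 and 32.

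Delayed development under BkF is a hypothesis that would set the BkF ratio against the change of the controls with time. Across genes, which are not independent replicates, Pearson r between the ratio and the change of controls at other time points was 0.01 and 0.08 at 48 and 96 hpf (change from 60 to 72 hpf) and -0.14 and -0.22 at 60 and 72 hpf (change from 48 to 96 hpf), the highest being 0.0825. With every interval between other time points r ran from -0.01 to 0.01 at 48 hpf, -0.20 to 0.13 at 60 hpf, -0.22 to -0.07 at 72 hpf and -0.06 to 0.08 at 96 hpf. A delay as the common source would need -0.2 or below at each time. At 48 and 96 hpf r stayed above that with every interval, so this prediction was not met. The bound written down beforehand against a delay was met by r at 48 and 96 hpf. The values cannot decide on a delay, however. The change of the controls up to 48 hpf was not sampled, and that from 72 to 96 hpf was left out for the 96 hpf ratio. A delay therefore stays open at 48 and 96 hpf, and the mixed or negative r at 60 and 72 hpf does not exclude it there.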
